A study of Arabidopsis thaliana with 6 samples.

How the data were processed

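The labels describe RNA-seq of whole Arabidopsis thaliana seedlings in 3 genotypes with 2 libraries each, prepared with a TruSeq kit from total RNA. Per the submitters' processing notes the authors used TopHat, DESeq and the TAIR10 build, and no versions are given in the sources used here. The authors deposited a table for each of the comparisons, IBH1-Ox against wild type and PRE1-Ox/IBH1-Ox against IBH1-Ox. Each table holds, per the file headers, the base mean of each group, a signal made by the authors as the mean over libraries of gene counts divided by size factors. The authors also deposited the ratio of the group means as a fold, its log2 in the first table, and the p-value and adjusted p-value of their test. The first table lists only called genes (1547, with a largest adjusted p of 0.0492 and folds of at least 1.5). The second holds 33518 genes, of which 24451 have a p-value and 9067 have a mean of 0 in both groups, and 5 summary entries for reads assigned to no gene. The authors' test gave a p-value for 3 of those entries, and none of them took part in the tests added here. Reads with more than 1 alignment made up 12.8% of the summed signal in IBH1-Ox and 10.3% in the double line, reads in no feature 1.05% and 0.959%, ambiguous reads 1.25% and 1.24%, and genes 84.9% and 87.5%.

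The deposited means are not counts of single libraries, so the design written before the data were examined used the authors' own test as the main result, at an adjusted p below 0.05. A group mean is a sum of whole reads of its libraries, each weighted by 1 step, and the steps were found from the lowest means. The authors' deposited means were then split into the pair of whole read counts that gave them, within the rounding of 10 significant digits plus a relative tolerance of 1e-10, and within 2e-09 for means under 100. The tolerance was set after several settings had been tried on these tables, with a look at how many means split, so the share that split is not an independent test of it. Of the group means above 0, 99.74% and 99.87% in the first table and 99.87% and 99.97% in the second split into exactly 1 pair. In simulations with 6 pairs of size factors, 98.32% to 99.71% of 8000 means split into 1 pair and 100% of these were right, while 0.15% to 0.6% of random values found a pair by accident. Of large simulated means, spread from 10000 upward, 6.75% to 55% split. The IBH1-Ox reads from both tables were equal for 1545 of 1545 genes. For 30 genes the means of the second table were not split, 27 of them with a mean of 34000 or more, which include most light-harvesting genes. Libraries carry no replicate number after this step and are told apart by the larger or smaller size factor, so no value is tied to a numbered sample. Over genes with at least 20 reads, the mean chi-square between the libraries of a group, which is 1 under sampling noise, was 3.61 for wild type and 2.91 for IBH1-Ox in the first table, and 2.25 for IBH1-Ox and 1.23 for the double line in the second. The medians, which are 0.455 under sampling noise, were 0.909, 0.769, 0.733 and 0.507 in the same order. The libraries of the double line thus lay close to sampling noise, but their mean exceeded 1 by more than the 0.0102 (SE) that noise gives over 19100 genes, and no pair was counted as 1 sample.

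The recovered reads of the second comparison were fitted with limma-voom (limma 3.58.1 in R 4.3.3), with the authors' size factors as library sizes and genes of mean normalized count 10 or more (19992 genes). This fit, and every use of recovered reads, was added after the tables had been seen. On simulated counts for that comparison over 19992 genes, with an assumed spread and 50 genes changed per fold size, limma called 18% at 1.5-fold, 72% at 2-fold, 88% at 4-fold and 98% at 8-fold, and 5.48% of its calls were false. Per-library values in the text are recovered reads divided by the authors' size factors. Intervals of ratios with 3 reads or fewer are exact binomial (Clopper-Pearson, 95%), and a count of 0 was set to a floor of 3 counts over the group.

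The 21 gene lists were fixed before the data were examined: helix-loop-helix and bHLH factors, expansins, xyloglucan endotransglucosylase/hydrolases, cellulose synthases, aquaporins, brassinosteroid genes, small auxin-up RNAs, Aux/IAA and GH3 genes, gibberellin genes, light-harvesting and RuBisCO genes, pathogen response, heat shock, cold and abscisic acid, flavonoid, clock, seed storage, root hair, stomatal lineage, vascular, meristem and organelle-encoded genes. Called members were compared with all other genes with a mean above 0 in the second table by Fisher's exact test, 2-sided, with Benjamini-Hochberg adjustment over the 42 tests of a comparison. For the first table this background may hold genes that were not tested there. Lists for iron uptake and aliphatic glucosinolates were written after the values had been seen, and their Fisher tests were adjusted separately, over 4 tests per comparison. In the second comparison lists were also tested with camera, at a preset correlation of 0.01 and at an estimated one, and with fry. Each was adjusted over all 23 lists. Camera sets a list against other genes, and fry tests its members alone. With an estimated correlation, camera has few degrees of freedom at 2 libraries per group. The median log2 fold change of a list was also placed among 10000 random lists of the same size, matched on mean expression. Adjustment over the list alone was possible only in the second comparison, because the first table lists only called genes.

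Named genes followed a rule fixed beforehand: IBH1, PRE1 and all measured members of the helix-loop-helix list, the 10 highest and 10 lowest called log2 fold changes per comparison among genes with a mean of 50 or more, up to 4 called members per list (2 where none was called), and the 10 genes with the largest opposite and the 5 with the largest same-direction changes. MLS, CRA1, CRC, OLEO1, MYB28, MAM1 and BCAT4 were named outside that rule, after their values had been seen. Gene names and gene order came from the TAIR10.1 annotation, in which 99.5% of the identifiers of the first table and 97.6% of the second matched, and no coordinates are given because the authors' build is TAIR10. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.

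The shared IBH1-Ox libraries were treated by simulating 100 draws of unchanged groups with spread estimated from the recovered reads. The simulation did not select genes by their first comparison, as the first table does. Alternatives were adjusted p limits of 0.01 and 0.1, fold limits of 2 and 1.5, a minimum mean of 50, an adjustment recomputed without genes of mean under 10, recentring on the median of genes of mean 100 or more, pseudocounts of 1 and 10, limma-voom with and without a filter, and each library left out in turn. The 1.5-fold limit in the second comparison, the limma fits and the library left out were chosen after seeing the data.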

Results

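The series measured messenger RNA by sequencing in whole Arabidopsis thaliana seedlings of the Col-0 ecotype, aged 5 days and kept in continuous light. The 6 libraries fall into 3 groups of 2. The groups are wild type, a line overexpressing myc-tagged IBH1 (IBH1-Ox), and a line that overexpresses YFP-tagged PRE1 besides IBH1 (PRE1-Ox/IBH1-Ox, the double line). IBH1 is a helix-loop-helix protein known to restrain cell elongation, and PRE1 is a small helix-loop-helix protein known to bind IBH1 and to promote elongation. The deposited tables give the authors' group means of normalized counts and their tests, and the whole reads of each library were recovered from those means. The IBH1-Ox libraries held 13942709 and 12208855 recovered reads over genes, and those of the double line held 9506402 and 7979224. For wild type only the genes of the first table could be read back, with 1124135 and 765807 reads. Nothing in the labels says that the replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical. Over genes with at least 200 reads in both libraries together, the SD of the log2 ratio between the libraries of a group was 0.19 for wild type and 0.186 for IBH1-Ox in the first table, and 0.154 for IBH1-Ox and 0.134 for the double line in the second.

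The first comparison set IBH1-Ox against wild type and asked which transcripts differ when IBH1 is overexpressed. IBH1 (AT2G43060) rose by 6.29 on the log2 scale in the authors' deposited table, with an adjusted p of 2.03e-118. Recovered reads put it at 179 and 138 normalized counts in the wild-type libraries and at 11790 and 12997 in the IBH1-Ox libraries. PRE1 (AT5G39860) rose by 1.25 in the authors' deposited table (adjusted p = 6.68e-10), from 66.7 and 56.4 to 140 and 151 normalized counts in the recovered reads. Among the fixed gene lists, 12 of 19 small auxin-up RNAs and 5 of 11 circadian clock genes fell, 7 of 32 xyloglucan endotransglucosylase/hydrolases rose, and expansins had called members in both directions.

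Of 19 measured small auxin-up RNAs, a family linked to auxin-driven cell expansion, 12 fell against 0.583 expected by chance (Fisher's exact test, 2-sided, adjusted p = 1.11e-12 over 42 list tests) and none rose. The authors' deposited table listed SAUR15 (AT4G38850) at a log2 fold change of -2.0, SAUR20 (AT5G18020) at -1.35, SAUR64 (AT1G29450) at -1.31 and SAUR16 (AT4G38860) at -1.03. Many members are close copies of their neighbours, among which the assignment of reads is uncertain. Fisher's exact test treats list members as independent, and camera, which allows for correlation between genes, was not run for this comparison. Of 11 clock genes 5 fell (expected 0.337, Fisher's exact adjusted p = 0.000223). They included the pseudo-response regulators PRR9 (-1.92), PRR7 (-1.09) and PRR5 (-0.72), and GI (-0.69), by the log2 fold changes of the authors' deposited table. Of 32 xyloglucan endotransglucosylase/hydrolases, which remodel the cell wall, 7 rose (expected 1.04, Fisher's exact adjusted p = 0.00088) and 1 fell. XTH15 rose by 0.88, XTH23 by 0.83 and XTH30 by 0.73, and XTH7 was the member that fell, by 1.1, in the authors' deposited table. Of 25 expansins, proteins that loosen the wall, 4 fell (expected 0.767, Fisher's exact adjusted p = 0.0465) and 3 rose (adjusted p = 0.196). EXPA1 fell by 1.43, EXPA11 by 1.17, EXPA8 by 1.14 and EXLB1 by 0.74 in the authors' deposited table. Of 6 root hair markers 3 rose (expected 0.196, Fisher's exact adjusted p = 0.00673), namely EXPA18, PRP3 and EXPA7, of which EXPA7 and EXPA18 are also in the expansin list.

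The list of helix-loop-helix and bHLH factors around IBH1 and PRE1 had 26 measured members, of which 5 fell (expected 0.798, Fisher's exact adjusted p = 0.00866) and 2 rose, the latter being IBH1 and PRE1. The authors' deposited table listed AIF1 (AT3G05800) at -1.47, AIF4 (AT1G09250) at -0.89, PAR2 (AT3G58850) at -0.84, PIF4 (AT2G43010) at -0.81 and IBL1 (AT4G30410) at -0.66. AIF1, AIF4 and IBL1 belong to the same family of atypical helix-loop-helix proteins as IBH1, and PIF4 is a bHLH factor that promotes elongation in response to light and warmth. The remaining 19 members were not listed in that table.

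Neither direction passed 0.05 for the other 15 lists. Gibberellin genes had 3 of 20 higher and 3 lower (Fisher's exact adjusted p = 0.121 for each), with GASA4 at 0.74, GASA1 at 0.63, GASA6 at -1.18 and GAI at -0.66 in the authors' deposited table. Of 17 Aux/IAA and GH3 genes 2 rose and 1 fell, with GH3.3 at 1.38, IAA29 at 1.1 and IAA3 at -0.69 in the authors' deposited table. A single called member was found among 12 aquaporins (TIP2;2, 0.94), 11 brassinosteroid genes (CYP90D1, -0.61), 15 pathogen response genes (PAD3, -0.78), 10 cold and abscisic acid genes (LTI30, -1.44), 13 flavonoid genes (A5GT, 1.73), 7 stomatal lineage markers (TMM, 0.63) and 6 vascular markers (SUC2, -0.90), by the authors' deposited table. Of 9 seed storage genes SESA2 rose by 3.36 and OLEO2 fell by 1.93 in the authors' deposited table. Of 129 genes of the organelle genomes 5 fell and none rose. No member was called among 18 light-harvesting and RuBisCO small subunit genes, 10 cellulose synthases, 8 heat shock genes and 7 meristem markers.

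Most of the genes with the lowest or highest log2 fold changes were locus identifiers without a symbol. AT3G28320 had 3 reads in wild type and 1511 in IBH1-Ox, a ratio of 619 with a 95% counting interval from 211 to 3006. AT3G43310 had 1 read and 376 reads, a ratio of 462 (82.5 to 18304). At the other end, AT3G47250 had 2681 reads in wild type and 2 in IBH1-Ox, a 1090-fold lower level (302 to 9009). AT3G28160 had 748 reads and 1 read, a 608-fold lower level (109 to 24066). Intervals cover counting error only. The authors' deposited table listed the glyoxylate cycle enzyme ICL (AT3G21720) at 4.70, AT5G44440 at 4.99 and AT3G27884 at 4.72, and the vicilin-like seed protein PAP85 (AT3G22640) at 6.09 with an adjusted p of 0.000587. PAP85 stood at 138 and 77.5 normalized counts in the IBH1-Ox libraries, a ratio of 1.78 between replicates, whereas ICL stood at 6348 and 6347.

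In total the authors' deposited table for this comparison listed 797 genes as higher and 750 as lower, each at an adjusted p below 0.05 and a fold of at least 1.5. The listed p-values imply about 24762 tests and 3647 genes below 0.05 without a fold limit, so the absence of a gene from that table does not show that it did not differ. With a limit of 2-fold, the small auxin-up RNA list alone stayed past the threshold (Fisher's exact adjusted p = 1.02e-08), and the root hair call ended at an adjusted p limit of 0.01 (0.484).

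The second comparison set the double line against IBH1-Ox and asked what added PRE1 changes when IBH1 is high. PRE1 rose by 6.01 ± 0.098 on the log2 scale (SE, limma-voom on recovered reads, 2 libraries per group, adjusted p = 1.8e-21), from 126 and 136 to 8465 and 8344 normalized counts. IBH1 was also higher, by 0.58 ± 0.042 (limma-voom adjusted p = 1.76e-10), at 16541 and 16523 normalized counts. All 14 light-harvesting genes fell, while 12 of 25 expansins, 6 of 12 aquaporins, 5 of 10 cellulose synthases and 8 of 13 flavonoid genes rose. Their lists passed Fisher's exact test, and none passed limma's camera test with an estimated correlation (adjusted p = 0.689, 0.3, 0.457, 0.361 and 0.3 in that order). With 2 libraries per group that form of camera has few degrees of freedom. Its estimated correlations exceeded the preset 0.01 for light-harvesting and RuBisCO genes (0.786), aquaporins (0.16) and flavonoid genes (0.121). For those lists the preset form may give p-values that are too small. The estimates lay below the preset for expansins (0.00237) and cellulose synthases (-0.123). None of the 23 lists passed the estimated form, those with a negative estimated correlation included, so its outcome does not decide on these calls. In fry all of these lists passed (adjusted p = 0.0325, 0.0108, 0.0325, 0.00781 and 0.0108 in the same order). Fry tests members alone, and most of the 23 lists passed it where 22.5% of all tested genes were called. A pass in fry therefore does not show that a list stands out from other genes. Of the 14 light-harvesting genes, only 3 were among the members that camera and fry could test. Genes said to rise or fall in this comparison passed the test in the authors' deposited table, and the log2 fold changes with SE come from limma-voom on the recovered reads.

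Of 25 expansins 12 rose and none fell (expected 3.17 and 2.45, Fisher's exact adjusted p = 0.000377 for higher), and 13 rose when adjusted over the list alone. Camera, with a preset correlation of 0.01, gave an adjusted p of 4.79e-07, and adjusted p = 0.3 with an estimated correlation. EXPA11 rose by 2.27 ± 0.064, EXPA3 by 1.2 ± 0.064, EXPA1 by 1.17 ± 0.058 and EXPA8 by 1.12 ± 0.065. Of 32 xyloglucan endotransglucosylase/hydrolases 9 rose and 3 fell (Fisher's exact adjusted p = 0.0463 for higher), with the same 9 and 3 by number when adjusted over the list alone. The camera adjusted p was 0.00971, and adjusted p = 0.3 with an estimated correlation. XTH7 rose by 1.98 ± 0.047 and XTH18 by 0.85 ± 0.058, and XTH15 stood at -0.80 ± 0.094. Of 10 cellulose synthases 5 rose (Fisher's exact adjusted p = 0.0167, and 5 adjusted over the list alone), namely CESA5 at 0.61 ± 0.053, CESA6 at 0.23 ± 0.046 and the secondary wall genes CESA7, CESA8 and CESA4 at 0.38 ± 0.077, 0.33 ± 0.085 and 0.32 ± 0.073, and these last 3 are also in the vascular list. In camera the adjusted p was 0.02 for this list, and adjusted p = 0.361 with an estimated correlation. Of 12 aquaporins, the water channels of the plasma membrane and tonoplast, 6 rose (Fisher's exact adjusted p = 0.0102, and 6 adjusted over the list alone, with 1 lower). For them camera gave an adjusted p of 0.00511, and adjusted p = 0.457 with an estimated correlation. TIP1;1 rose by 0.70 ± 0.042 and PIP2;1 by 0.45 ± 0.041. Among random lists matched on mean expression, the list medians lay at percentile 100 for expansins and 95.9 for xyloglucan endotransglucosylase/hydrolases. For cellulose synthases and aquaporins they lay lower, at percentile 82 and 83.2. At a limit of 2-fold 0 cellulose synthases and 0 aquaporins were called, and 2 xyloglucan endotransglucosylase/hydrolases (Fisher's exact adjusted p = 0.546). A background of genes of mean 50 or more also ended the call of the latter (0.118).

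Of 18 genes of light-harvesting proteins and RuBisCO small subunits 14 fell (expected 1.76, Fisher's exact adjusted p = 6.24e-10) and 4 rose, with 14 and 4 when adjusted over the list alone. Camera, in which 5 members could be tested, did not call this list (adjusted p = 0.164, and adjusted p = 0.689 with an estimated correlation). Fry on the same 5 members passed as lower (adjusted p = 0.0325). Of these members 3 were light-harvesting genes, and the others were RuBisCO genes, which rose. Neither test thus covers the 14 light-harvesting genes as a set. The 14 that fell were the light-harvesting genes, with a median log2 fold change of -1.48 and a range from -2.85 to -0.66 in the authors' deposited table, and the 4 that rose encode RuBisCO small subunits. LHCB2.2 (AT2G05070) stood at -2.85 ± 0.051 and LHCB2.1 (AT2G05100) at -2.31 ± 0.052 (limma-voom adjusted p = 7.13e-21 and 3.13e-19). LHCB1.1 and LHCB1.2 are near-identical copies whose reads are uncertain, and their IBH1-Ox means were too high to be split into libraries. Whether LHCB2.1 and LHCB2.2 share reads in the same way was not examined. The light-harvesting genes made up 6.04% of the authors' summed gene signal in IBH1-Ox and 2.32% in the double line. Of 11 clock genes 5 fell (Fisher's exact adjusted p = 0.0116) and 2 rose, and 5 fell and 5 rose when adjusted over the list alone. The list's median was 0.15 while camera placed it downward without a call (adjusted p = 0.27, and adjusted p = 0.595 with an estimated correlation). In fry the clock list passed as lower (adjusted p = 0.0255). PRR7 stood at -2.04 ± 0.11, PRR9 at -1.28 ± 0.34, CCA1 at -1.06 ± 0.071 and LHY at -0.93 ± 0.06, and ELF4 rose by 0.68 ± 0.084. With a background of genes of mean 50 or more the clock call ended (Fisher's exact adjusted p = 0.108).

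Of the 26 helix-loop-helix and bHLH factors 9 rose (Fisher's exact adjusted p = 0.0146), IBH1 and PRE1 included, and 10 fell (adjusted p = 0.000576). PRE1 was overexpressed in the double line by design, and the list was not tested without PRE1 and IBH1. Adjusted over the list alone the counts were 9 and 11. The list had a median of -0.13 while camera placed it upward without a call (adjusted p = 0.696, and adjusted p = 0.88 with an estimated correlation). In fry the list passed as higher, with IBH1 and PRE1 included (adjusted p = 0.0305). AIF1 rose by 2.85 ± 0.12, IBL1 by 2.59 ± 0.13, AIF4 by 1.54 ± 0.11, AIF2 by 1.14 ± 0.091, PAR2 by 1.06 ± 0.16 and BES1 by 0.80 ± 0.058, and AIF3 was at 0.35 ± 0.073. PIF4 stood at -2.41 ± 0.14, PIF5 at -2.19 ± 0.093 and PIF1 at -0.50 ± 0.093. Other genes of the PRE family stood lower, with PRE2 at -2.14 ± 0.47, PRE6 at -1.66 ± 0.15 and PRE3 at -0.70 ± 0.14, and PRE5 had 18 reads in IBH1-Ox and 0 in the double line, at least 3.63-fold lower against a floor of 3 counts over the group, with an exact 95% counting limit of 2.63-fold. HBI1, a bHLH activator of elongation that IBH1 is known to bind, stood at -0.61 ± 0.064, BEE1 at -0.51 ± 0.16 and BEE3 at -0.41 ± 0.11. Adjusted p in the authors' deposited table did not pass for PIF3 (0.0571), BZR1 (0.309), PAR1 (0.378), BEE2 (0.68), HFR1 (0.726), BPE (1) and PRE4 (1).

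**Figure D1:**
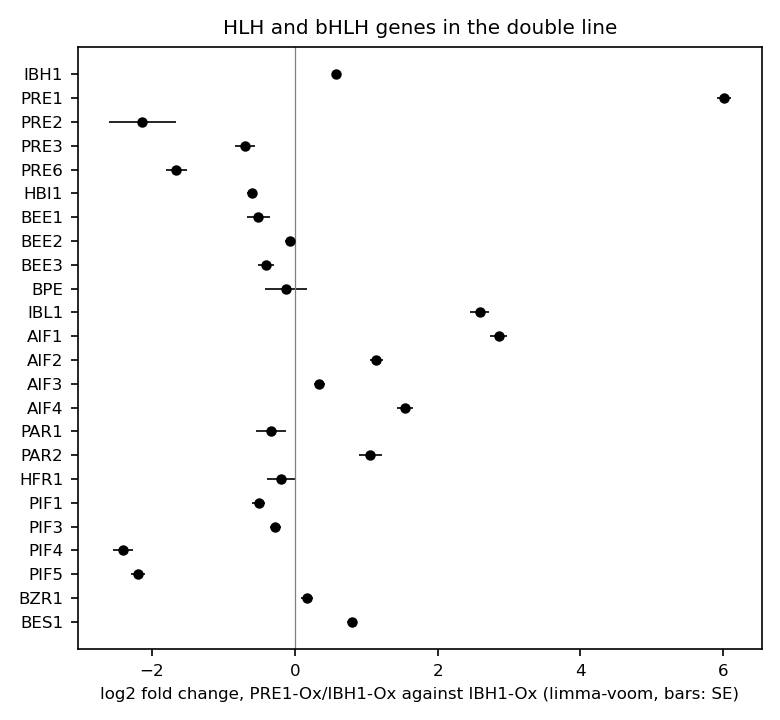
Log2 fold change of the double line against IBH1-Ox (horizontal axis) for the 24 helix-loop-helix and bHLH genes in the limma-voom fit. Points are estimates from 2 libraries per group and bars are SE, with PRE1 at 6.01, AIF1 at 2.85 and PIF4 at -2.41.

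Of 13 flavonoid and anthocyanin genes 8 rose and none fell (Fisher's exact adjusted p = 0.000432), and 10 rose when adjusted over the list alone. Their camera adjusted p was 2.16e-06, and adjusted p = 0.3 with an estimated correlation. Chalcone synthase CHS rose by 1.24 ± 0.048, A5GT by 1.18 ± 0.16 and CHI by 0.90 ± 0.079. Of 17 Aux/IAA and GH3 genes 8 fell (Fisher's exact adjusted p = 0.000576) and 3 rose, with 8 and 3 when adjusted over the list alone. These had a camera adjusted p of 0.0196, and adjusted p = 0.577 with an estimated correlation. GH3.3, GH3.6 and GH3.5, enzymes that conjugate auxin to amino acids, stood at -2.35 ± 0.18, -1.81 ± 0.072 and -1.18 ± 0.088, and IAA17 rose by 0.74 ± 0.06. Of 10 cold and abscisic acid genes 5 rose (Fisher's exact adjusted p = 0.0167) and 7 when adjusted over the list alone, among them LTI30 at 0.89 ± 0.082 and ERD10 at 0.83 ± 0.059. Here camera gave an adjusted p of 7.68e-05, and adjusted p = 0.3 with an estimated correlation. Of 20 gibberellin genes 7 rose (Fisher's exact adjusted p = 0.0293) and 4 fell, with 9 and 4 when adjusted over the list alone. This list was not called in camera (adjusted p = 0.0594, and adjusted p = 0.392 with an estimated correlation), but passed in fry as higher (adjusted p = 0.0187). The DELLA gene RGL1 rose by 1.11 ± 0.13 and the receptor gene GID1A by 0.53 ± 0.084. Of 129 organelle genes 3 rose and 1 fell, fewer than the 16.4 and 12.6 expected (Fisher's exact adjusted p = 0.000432 for each), and 3 and 0 when adjusted over the list alone. Camera did not call them (adjusted p = 0.501, and adjusted p = 0.88 with an estimated correlation), nor did fry (adjusted p = 0.829). Both organelle calls ended with a background of genes of mean 50 or more (Fisher's exact adjusted p = 0.374 for higher and 0.39 for lower). They also ended at a limit of 2-fold (0.931 and 0.457), as did those for gibberellin genes (0.931) and for cold and abscisic acid genes, of which 0 were called there.

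The remaining lists did not pass in either direction, nor in camera with the preset or an estimated correlation. In fry the vascular list alone among them passed, as higher (adjusted p = 0.0325). Of 11 brassinosteroid genes 4 rose (Fisher's exact adjusted p = 0.101), namely BR6OX1, DWF4, BR6OX2 and CYP90D1, which act in biosynthesis, and 1 fell, with 4 and 2 when adjusted over the list alone. Of 7 stomatal lineage markers SPCH, TMM and MYB60 fell (Fisher's exact adjusted p = 0.0678), and 3 when adjusted over the list alone. Of 6 vascular markers the secondary wall cellulose synthases CESA4, CESA7 and CESA8, which the cellulose synthase list also holds, rose (Fisher's exact adjusted p = 0.0797), and 3 when adjusted over the list alone. Of 19 small auxin-up RNAs SAUR63 fell, and 0 when adjusted over the list alone. Among 15 pathogen response genes PAD3 and PR5 rose and WRKY33 and SID2 fell, with 2 and 3 when adjusted over the list alone, and PR5 rested on 1 and 11 reads, a ratio of 18.4 (95% counting interval 2.68 to 793). Among 7 meristem markers SHR rose and PLT1 fell, and 1 and 1 when adjusted over the list alone. Of 9 seed storage genes OLEO2 rose by 1.37 ± 0.15 and SESA1 had 2 and 15 reads, a ratio of 12.6 (2.92 to 113), with 2 when adjusted over the list alone and a list median of -0.36. None of 8 heat shock genes and none of 6 root hair markers passed the test in the authors' deposited table, and 0 did when adjusted over the list alone. HSP70 stood at 0.57 ± 0.13 in limma-voom, whose adjusted p was 0.00162, and RSL4 at -0.53 ± 0.22 (0.0564).

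**Figure D2:**
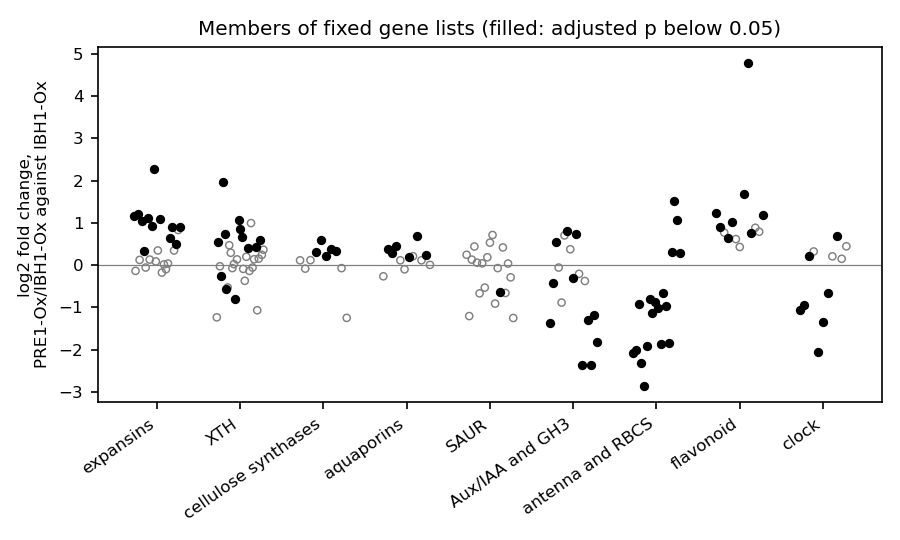
Log2 fold change of the double line against IBH1-Ox in the authors' deposited table (vertical axis) for the members of 9 of the fixed lists (horizontal axis). Filled points have an adjusted p below 0.05, and the 14 light-harvesting genes lie below 0.

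Outside the lists, AT4G08110 had 1 read in IBH1-Ox and 384 in the double line, a ratio of 643 (95% counting interval 115 to 25455). CYP82C4 (AT4G31940) rose by 5.53 ± 0.35 and NAS2 (AT5G56080) by 4.17 ± 0.36. The iron transporter gene IRT1 rose by 3.79 ± 0.15 and the ferric reductase gene FRO2 by 3.67 ± 0.17. At the other end stood AT3G55240 at -4.62 ± 0.39, the ferric reductase family gene FRO4 at -4.55 ± 0.35, AT4G36850 at -4.23 ± 0.13, AT5G44440 at -4.00 ± 0.14 and SEN1 at -3.54 ± 0.14.

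In total 3104 genes were higher and 2392 lower among 24451 tested genes in the authors' deposited table (22.5% called). A limit of 1.5-fold, as in the first table, left 1360 and 1134. limma-voom on recovered reads called 4158 genes higher and 3461 lower among 19992, and without the double-line library of larger or of smaller size factor it called 2083 or 2216 lower. On limma calls, 5 of the list calls above ended, with adjusted p of 0.11 for light-harvesting genes (of which few could be split), 0.11 for xyloglucan endotransglucosylase/hydrolases, 0.169 for helix-loop-helix genes higher, 0.0999 for clock genes and 0.0946 for organelle genes lower.

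The third question was whether genes changed in IBH1-Ox moved back when PRE1 was added. Of the 1547 genes listed in the first comparison, 867 were also called in the second comparison, by the tests of the authors' deposited tables. Of these, 779 (89.9%) changed in opposite directions while 88 changed the same way (Fisher's exact test, 2-sided, p = 6.54e-139). That p-value takes genes as independent and makes no allowance for the IBH1-Ox libraries that both comparisons share. By direction, 383 genes were higher and then lower (78 expected from independent lists) and 396 lower and then higher (95.2 expected). By contrast, 41 were higher in both (101 expected) and 47 lower in both (73.4 expected). With the 1.5-fold limit of the first table also set in the second comparison, 662 changed in opposite directions and 59 the same way. CYP82C4, NAS2, IRT1, FRO2, CYP79F1, AT4G08110 and AT4G22485 were lower and then higher, and AT5G44440 and AT1G48660 were higher and then lower. In the authors' deposited table CYP82C4 went from -5.81 to 5.40, IRT1 from -4.12 to 3.75, CYP79F1, which acts in glucosinolate synthesis, from -4.48 to 3.32, and AT5G44440 from 4.99 to -3.97. EXPA1, EXPA8, EXPA11, XTH7, AIF1 and IBL1 were also lower and then higher. Of the 19 small auxin-up RNAs, 12 of which fell in IBH1-Ox, none was called higher in the double line. The naming rule for same-direction genes gave PRE1 and BHLH100, higher in both, and CIPK20, AT1G15125 and CYP71B4, lower in both. Of the genes named under other parts of the rule, IBH1, AT3G28320, A5GT, GASA4 and XTH23 were also higher in both, and PIF4, PRR7, PRR9, GI, SAUR63 and AT3G55240 lower in both. In the authors' deposited table PIF4 stood at -0.81 and -2.42.

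**Figure D3:**
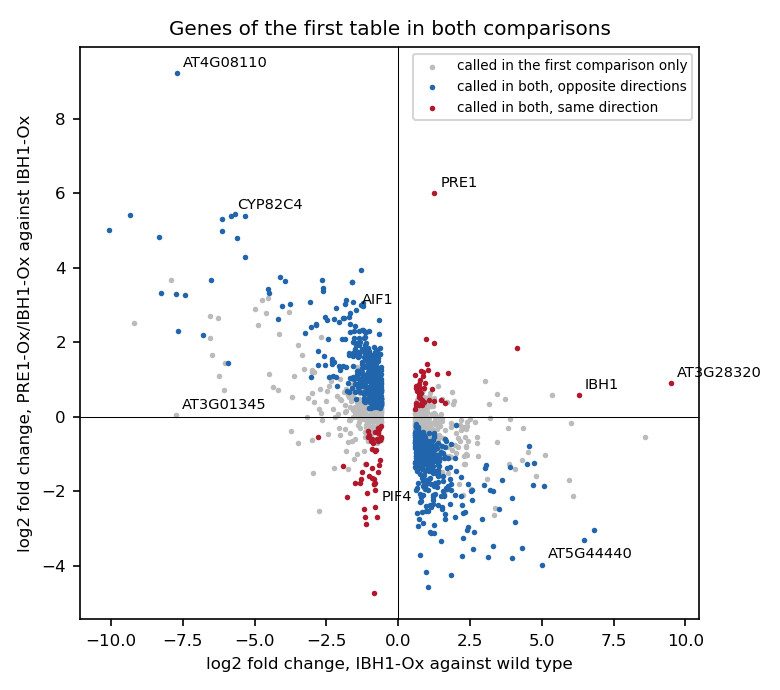
Log2 fold change of IBH1-Ox against wild type (horizontal axis) and of the double line against IBH1-Ox (vertical axis) in the authors' deposited table, 1 point per gene of the first table with finite values (1543 genes). The 779 genes called in opposite directions lie in the upper left and lower right parts, except for 1 gene at 0 in the double line that is not drawn, and the 88 called in the same direction lie in the others.

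Both comparisons contain the same IBH1-Ox libraries, which gives opposite signs by chance. Across genes, which are not independent replicates, the log2 fold changes correlated at -0.663 with a covariance of -1.53, and 82.4% had opposite signs. In 100 simulated draws of unchanged groups sharing those libraries, the mean correlation was -0.456, the mean covariance -0.0331 and the mean share of opposite signs 65.4%, so the covariance lay 1.5 below the simulated one. With a different IBH1-Ox library in each comparison the covariance was -1.26 or -1.27 and the share of opposite signs 81.7% or 81.9% over 1516 genes, and among the genes called in both 775 had opposite and 88 the same signs. The calls themselves were made with the shared libraries, so part of the excess of opposite calls over independent lists may come from them.

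A level set across the separately normalized tables, through the factor 1.118 between the authors' IBH1-Ox means, placed the double line against wild type. Genes higher in IBH1-Ox had a median log2 level of 0.914 in that line and 0.375 in the double line, and genes lower in IBH1-Ox had -1.02 and -0.481. Within 1.5-fold of wild type were 418 (52.6%) of the former and 358 (47.9%) of the latter. All of these genes had been listed for a difference of at least 1.5-fold, so none lay within that limit in IBH1-Ox. Selection on that fold alone can bring some genes inside the limit, and how many was not estimated. Still over 1.5-fold from wild type in the first direction were 305 and 327 genes, and past it by over 1.5-fold the other way were 72 and 63. No test was made across the tables.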

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

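The 1.5-fold limit, the limma fits and the libraries left out were alternatives chosen after seeing the data. A limit of 2-fold left 345 higher and 388 lower genes in the first comparison, 566 and 519 in the second, and 287 opposite and 18 same-direction genes in the overlap. List calls past 0.05 then numbered 1 and 7, since fewer genes were called. In the second comparison this ended the calls for aquaporins, cellulose synthases and cold and abscisic acid genes (0 genes called), xyloglucan endotransglucosylase/hydrolases (0.546), gibberellin genes (0.931) and organelle genes (0.931 higher, 0.457 lower). A 1.5-fold limit in the second comparison left 1360 and 1134. limma-voom calls gave 9 list calls in the second comparison, and leaving out each library in turn gave 8 to 13. On limma calls, leaving out the IBH1-Ox library of larger size factor ended the call for helix-loop-helix genes lower (0.0898), and leaving out the double-line library of larger size factor ended those for cellulose synthases (0.114), aquaporins (0.0955) and gibberellin genes (0.0726). The call for organelle genes higher, at 0.0232 on limma calls, ended without the double-line library of larger (0.353) or smaller (0.144) size factor and without the IBH1-Ox library of smaller size factor (0.111). Without a double-line library seed storage genes passed as lower (0.0449 and 0.0371). A background of genes of mean 50 or more ended the calls for xyloglucan endotransglucosylase/hydrolases (0.118), clock (0.108) and organelle genes (0.374 higher, 0.39 lower) and added stomatal lineage genes lower (0.0372), and a limit of 0.01 ended that for cellulose synthases (0.193). Measured against the authors' own counts, no number of called genes moved by over 1.5 times at settings other than the fold limits and recentring. Fits with a library left out were not measured against the limma fit of all libraries for this. No named call changed direction. Of the alternative log2 fold changes of named genes, 97 moved by more than the spread between replicates and 1591, recentred values included, did not. With 1 library left out, limma-voom called 3032 to 4048 genes higher and 2083 to 3499 lower, where the lone library is assumed to vary like the others. Both low lower counts, 2083 and 2216, came without a double-line library (of larger and of smaller size factor), and the cause was not tested. BEE1 lost its limma call without the IBH1-Ox library of larger size factor. BEE1, BEE3, XTH23, CESA6 and SAUR63 lost it without the double-line library of larger size factor, and TMM, SAUR63, SID2, PLT1 and ATCG00180 without the other. In the first comparison 717 to 748 higher and 696 to 718 lower genes kept a 1.5-fold change with a library left out. Recentring shifted every log2 fold change by the same 0.00633 with the authors' p-values kept, so it could hardly move a count and shows no stability. No paired analysis was possible because the recovered libraries carry no replicate number. Not run were an adjusted p of 0.1, a recomputed adjustment and recentring in the first comparison, whose table lists only called genes. Other count models on the recovered reads were not run either. Depth limits weakly expressed genes, whose ratios rest on few reads.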

Other observations

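All tests and both gene lists in this part were chosen only after the values had been seen. Fisher's tests of these lists were adjusted over their own 4 tests per comparison. Because the lists were written with these values in view, their p-values, in camera too, are no independent evidence. Genes of iron uptake formed a group that the fixed lists did not hold. Of 18 measured members 6 fell in IBH1-Ox (Fisher's exact adjusted p = 2.21e-05) and 2 rose, and in the double line 12 rose (adjusted p = 3.04e-07) and 1 fell against IBH1-Ox. The authors' deposited table listed IRT1 at -4.12 and then 3.75, FRO2 at -3.95 and then 3.65, NAS2 at -5.32 and then 4.28, and the regulator BHLH100 at 1.24 and then 1.98. The list stood out in camera with a preset correlation (adjusted p = 2.99e-09) and not with an estimated one (adjusted p = 0.3), which no list passed.

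Genes of aliphatic glucosinolate synthesis formed another group. Of 16 members 15 fell in IBH1-Ox (Fisher's exact adjusted p = 1.09e-21) and 13 rose in the double line (adjusted p = 3.35e-09). CYP79F1 went from -4.48 to 3.32, the regulator MYB28 from -1.09 to 1.04 and MAM1 from -2.40 to 1.07 in the authors' deposited table. BCAT4 stood at -2.09 and then 0.09 there, and its second value did not pass the test. In camera with an estimated correlation, which no list passed, the adjusted p was 0.3, against 2.21e-09 with the preset one.

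A first pattern, for which segments of another strain carried by the transgenic line may account, was the position of the 38 genes that differed by at least 32-fold between IBH1-Ox and wild type, IBH1 left out. In gene order their median distance to the nearest other such gene was 91.5 genes against 316.5 in random sets of other called genes (p = 0.0003, permutation test), and 22 of them lie on chromosome 3, which holds 23.3% of called genes. With 1 gene kept per run of neighbours within 10 positions, the close spacing no longer passed (permutation p = 0.202, 32 genes, 284.5 against 379.5), which leaves tandem copies open for the spacing. A second test, added only after that result was seen, compared their counts over all chromosomes with those of other called genes (chi-square, permutation p = 0.0001, the smallest the permutations can give), with 18 of the 32 on chromosome 3 against 7.19 expected, which argues against tandem copies for the uneven chromosome counts. Repression by IBH1 that PRE1 relieves stays undecided, since the median rise of the 28 lowered genes in the double line, 43.4% of their log2 fall against 49.5% for 84 genes lowered 4-fold to 32-fold (permutation p = 0.599), rests for 19 of them on 3 or fewer IBH1-Ox reads and pools 19 genes that stayed below 10% of wild type, 14 of them among the 15 on chromosome 3, with 9 that came back further.

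A second pattern was the fall of the 14 light-harvesting genes in the double line, at a median log2 fold change of -1.48. A shift in the share taken by abundant transcripts would lower other abundant genes too, but the median of 144 others with a mean of 10000 or more was 0.259. A different clock phase at harvest could contribute. The morning genes CCA1, LHY, PRR9 and PRR7 averaged -1.35 and the later ones 0.197 (exact permutation p = 0.00303, the smallest of 330 arrangements), but their falls had been seen before the test, so it does not decide. The morning genes PRR9 and PRR7 and the later genes GI (-0.69) and PRR5 (-0.72) also fell in IBH1-Ox against wild type in the authors' deposited table. None of the light-harvesting genes was listed there. The seedlings were kept in continuous light, and any phase goes with genotype here, so phase and an effect of PRE1 both stay open.

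The last pattern was the higher level of the glyoxylate cycle genes ICL and MLS in IBH1-Ox. Seeds that lagged in germination in 1 of the IBH1-Ox libraries could raise such genes, and the seed genes PAP85, SESA2, CRA1 and CRC differed between those libraries by ratios of 1.78, 1.87, 2.23 and 2.6, while the oleosin genes OLEO1 and OLEO2 differed by 1.46 and 1.06. ICL and MLS differed by 1.07 at most, which argues against a lag in 1 library as their source. Slower seedling development in both libraries was not tested and stays open, as does an effect of IBH1, although OLEO2 was lower in IBH1-Ox than in wild type (-1.93 in the authors' deposited table) where SESA2 and PAP85 were higher.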
